A study of Mus musculus with 6 samples.

How the data were processed

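Ovary RNA of C57Bl/6J mice was measured on spotted 2-colour cDNA arrays carrying clones of a mouse embryo gene set. Per the file headers, each value is a log2 ratio with the later day (day 2 or day 4 after birth) in Cy5 over day 0 in Cy3. All 6 arrays had the same dye orientation per the labels, so that a gene-specific dye effect cannot be told apart from a change against day 0. The authors deposited, for each probe and array, 4 repeat log2 ratios, their mean, a mean log2 intensity over both channels, and 3 kinds of flags. The headers do not define the flags, which were read here from the values as marks of low signal, of repeats that differ and of failed areas. The medians of the deposited log2 ratios were near 0 on every array, so that the authors had normalized them. The authors used R 1.7.1 per the labels, and their background correction and normalization method are not given in the sources used here. The deposited value table holds the authors' mean log2 ratio per probe and array and was used only as an alternative.

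The mean of the 4 repeats was taken per probe and array, with no further normalization. The 6 arrays were grouped as 3 of day 2 and 3 of day 4. Per the labels, array 3 of both ages was hybridised with the same day 0 RNA, and the other 4 arrays each had a day 0 RNA of their own. A probe was tested when it had a value on at least 2 arrays of each age, which held for 8135 of 8272 probes. Clone names were turned into gene names: 1755 probes through a mouse gene table, 442 probes by hand from 325 older names, and 2656 probes by the annotation name alone. The other 3419 probes had no gene name and were tested without one. The gene table served for names only, and clones were not placed on the genome. For arrays, the number of arrays limits the precision: the median standard error was 0.17 (log2) for day 2 against day 0, 0.19 for day 4 against day 0 and 0.26 for day 4 against day 2.

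Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per age fitted to all 6 arrays, moderated variances without trend and not robust, and 2-sided tests. P-values were adjusted by the Benjamini-Hochberg method over all probes tested, with an adjusted p under 0.05 as the threshold. The prior had 2.03 degrees of freedom. Each standard error (SE) given with a log2 value comes from this fit, and n is the number of arrays of the later age with a value. The fit pools the spread of both ages, so that the spread of the day 2 arrays enters the SEs and tests at day 4. Day 4 against day 2 is an indirect comparison through day 0, in which a dye effect common to all arrays cancels.

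Of 26 gene lists fixed beforehand, 23 had at least 5 measured genes and were tested with limma's camera at a preset correlation between genes of 0.01. The brightest probe stood for each gene, and p-values were adjusted over the 23 lists of a comparison. Ribosomal, oxidative phosphorylation and proteasome lists were drawn from gene names, and the others were written gene by gene. Camera with an estimated correlation and fry, a rotation test, were run on the 2572 genes with values on all 6 arrays, where 17 lists had enough genes, so that these runs differ from the first one in their genes as well. Lists of neurotrophins and their receptors (1 gene measured), of leukocyte and macrophage markers (4 genes) and of ovarian surface epithelium markers (4 genes) were not tested.

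Genes were named by a rule with 3 parts. The first part took genes past the test with the same sign on all 3 arrays, up to 12 in each direction by size, or, where no gene passed, the 5 smallest p-values in each direction. The second took up to 4 members with the smallest p-values from each list past its test, and the third took 36 genes of ovarian interest whatever their values, of which 10 were measured. 1 gene that the first part named is not reported here, for a reason unrelated to its values. Lists, rule, tests and the first set of alternatives were chosen before the data were examined. Other genes that are named were chosen after their values were seen.

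The code was tested on simulated data with 200 changed probes among 8135, drawn from the spread of all 6 arrays. At a log2 change of 1 it recovered 35.5% of them for day 4 against day 0 and 9% for day 4 against day 2, and at a log2 change of 2 it recovered 74.5% and 61.5%. False calls numbered 1 and 3 at a log2 change of 1 and 9 and 7 at a log2 change of 2, in the same order, and 0 by limma in the unchanged comparison. With the spread of the day 4 arrays alone it recovered 70.5% and 51.5% at a log2 change of 1 and 92.5% and 85.5% at a log2 change of 2, with 8, 9, 9 and 16 false calls. Among 23 simulated lists it found the 1 that was shifted, by a log2 of 0.5, and no other. All values simulated for these checks of the code were drawn independently over genes and arrays. False calls that come from correlated genes or arrays were therefore not tested.

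Alternatives were median centring, scale normalization between arrays, leaving out the dimmest 30% of probes, the median of a probe's spots, the authors' value table, each array left out in turn, a trended and robust variance, adjusted p thresholds of 0.01 and 0.10, spots kept as duplicates (correlation 0.748), a fit to the 3 arrays of an age alone, the replicate number as a block, an estimated correlation, fry, and the mean over a gene's probes. Added after seeing the data were the sign of day 2 array 1 or of day 2 array 2 turned, these arrays left out together, array 3 of both ages left out, values with the authors' flags left out, a loess curve on intensity removed, and the preset correlation on the genes with values on all 6 arrays. The flags left out were those read as low signal and as repeats that differ, and not those read as failed areas. The comparison of the probes called at day 4 with simulated top probes, by their sign at day 2, was also added then. The overlap of the comparisons was set against 100 simulated sets of unchanged arrays in which 2 arrays shared a day 0 RNA. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Scanner intensities per channel were not analysed here. Where a share in the Cy3 channel is given below, that channel was rebuilt from the normalized log2 ratios and the mean log2 intensities. Such a share comes out midway between the bounds set for it, 0.33 and 0.67, where differences in ratio and in intensity are unrelated.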

Results

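Ovaries of newborn mice (day 0) were compared with ovaries at day 2 and day 4 after birth on 6 arrays, each with ovary RNA of a later day against day 0 RNA. The series text places the assembly of follicles at day 2 in this strain and the first growth of the new follicles just after it, and asks which genes change over that time. There were 3 arrays per age, each with its own later RNA, and the values are log2 ratios of the later day over day 0. Day 2 arrays 1, 2 and 3 had values for 8272 probes each, and day 4 arrays 1, 2 and 3 for 7775, 8272 and 5630. Median mean log2 intensity ran from 8.74 on day 2 array 1 to 10.58 on day 4 array 3. The direction of the day 2 values is not settled. Day 2 arrays 1 and 2 ran opposite to each other across probes (r −0.675, 8272 probes, which are not independent replicates), although both are stated to have the same dye orientation and the same conditions. For day 2 against day 0 and day 4 against day 2, the numbers of probes and lists that passed and the tests of the lists past the threshold are therefore also given with the sign of either array turned. So are the number of probes called at day 4, the correlation between the mean log2 ratios of the ages and the gene values whose sign this changed. Other values that rest on the day 2 arrays are in the stated direction unless said otherwise. Across probes, day 4 arrays 1 and 2 had r 0.752, and array 3 of both ages, which shared a day 0 RNA, had r 0.767.

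**Figure D1:**
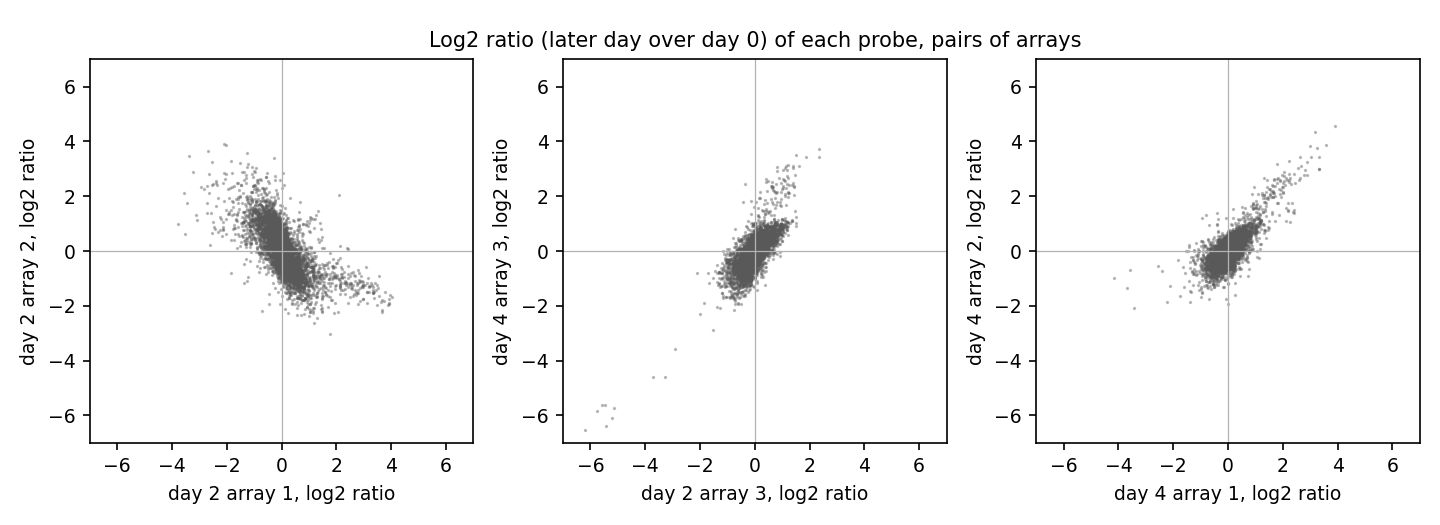
Log2 ratio (later day over day 0) of each probe on 1 array against another, with a point per probe, for 3 pairs of arrays. Day 2 arrays 1 and 2 run in opposite directions (r −0.675), while array 3 of both ages (r 0.767) and day 4 arrays 1 and 2 (r 0.752) run together.

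Between day 0 and day 4, genes known from the oocyte rose. Gdf9, a growth factor secreted by the oocyte, rose 7.61-fold (log2 2.93 ± 0.18, SE, n = 3, adjusted p = 0.00875), while 2 other probes of Gdf9 did not pass (3.38 ± 0.52, adjusted p = 0.0762, the brightest, and 1.81 ± 0.34, adjusted p = 0.128). The SE of the brightest probe comes mostly from day 2: its standard deviation was 0.06 over the day 4 arrays and 1.55 over the day 2 arrays. H1f8, the linker histone of oocytes, rose 5.25-fold (2.39 ± 0.12, n = 3, adjusted p = 0.00862). Nlrp14, a member of the NLR family expressed in oocytes, rose 12.5-fold (3.64 ± 0.41, n = 3, adjusted p = 0.033). Astl, the oocyte protease that acts on the egg coat after fertilisation, rose 7.31-fold (2.87 ± 0.23, n = 3, adjusted p = 0.0103). The background is day 0 RNA on the same array, at a log2 ratio of 0, and with 1 dye orientation these values also hold any gene-specific dye effect.

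The other named genes with the largest rises that are reported here spanned log2 1.94 to 3.65. Fbxw27, of the F-box family, rose by 3.65 ± 0.30 (n = 3, adjusted p = 0.0105), and its other probe rose by 2.49 ± 0.26. The genes named 2'-5' oligoadenylate synthetase 1C (3.13 ± 0.24) and Oas1d (3.05 ± 0.30) belong to a family known for its response to double-stranded RNA. Oas1d is also a member of the list of oocyte and primordial follicle genes described below. Ddias rose by 2.67 ± 0.33 and Btg4, an adaptor in the decay of maternal mRNA, by 1.97 ± 0.25. Thyrotroph embryonic factor, a transcription factor, rose by 2.27 ± 0.27, and Spopl, an adaptor of a ubiquitin ligase, by 1.94 ± 0.22 (n = 3 each). For these 2 genes the rise holds for 1 probe: the other probe of Spopl had −0.31, and the other probes of thyrotroph embryonic factor had −0.07 and 1.03, none past the test. Of the other probes of Btg4, 1 passed (1.52 ± 0.19) and the brightest did not (0.95 ± 0.32), and those of 2'-5' oligoadenylate synthetase 1C had 1.81 ± 0.92 (the brightest) and 2.08 ± 0.31 (n = 2 each), neither past the test. Beyond this rule, 7 more named genes rose: Appl1, Rgs12, exonuclease 1, Slx4ip, Trpm7, Pramel48 and Depdc7.

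In all, limma called 39 probes higher and 0 lower at day 4 than at day 0. They spanned log2 0.81 to 3.65 (1.76-fold to 12.5-fold), 22 belonged to 19 named genes and 17 had no gene name. 34 of them had a value of the same sign on all 3 arrays, a count that leaves out probes without a value on 1 array. On day 4 arrays 1, 2 and 3, 38, 39 and 35 of them had a positive value. At an unadjusted p under 0.05 there were 756 probes, 407 higher and 349 lower. The count was 0 without day 4 array 1, 2 or 3 (339, 380 and 588 probes at an unadjusted p under 0.05), 71 without day 2 array 1, 16 without day 2 array 3, 45 with the sign of day 2 array 1 turned, 0 with that of day 2 array 2 turned and 0 without array 3 of both ages (897 and 433 at an unadjusted p under 0.05). Other choices gave up to 374, of which 156 were lower, when the spots of a probe were kept as duplicates.

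**Figure D2:**
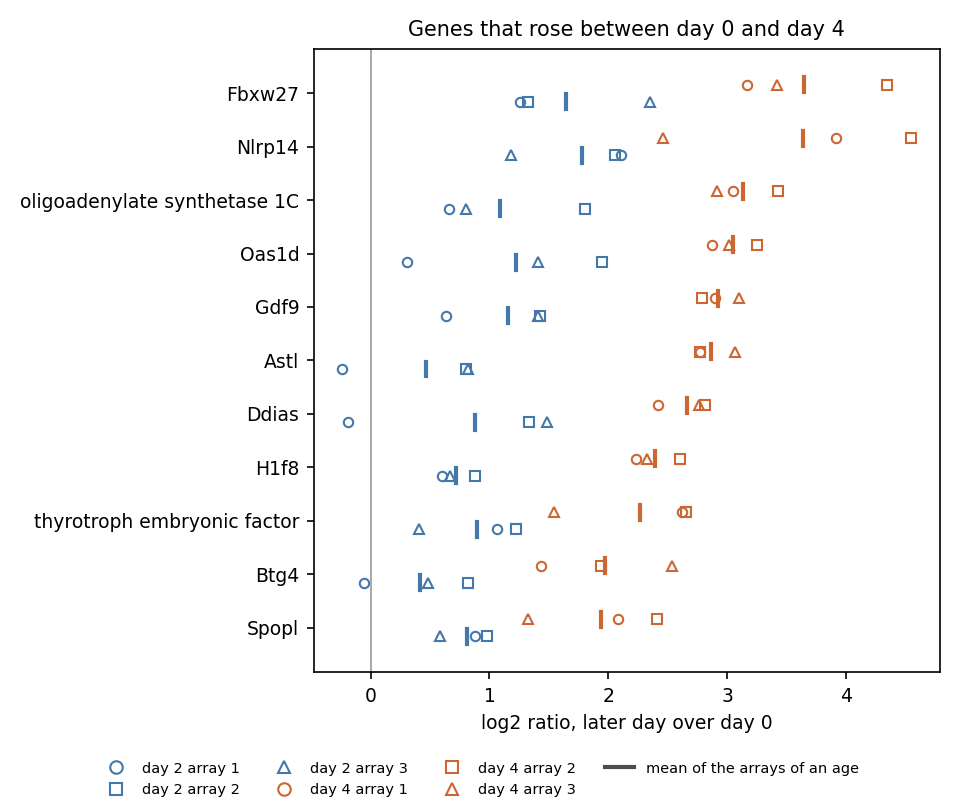
Log2 ratio (later day over day 0) per array of 11 of the named genes with the largest rises at day 4, with a symbol per array and a bar at the mean of an age. All day 4 values lie above 1, and the mean of each gene is lower at day 2 than at day 4.

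Among the lists, the oocyte and primordial follicle genes shifted upward at day 4. Of 21 measured members, 19 had a positive log2 ratio, with a median of 0.88 and a mean of 1.18 (adjusted p = 3.27e-16). Over all probes 4 rose and 0 fell (limma), and adjusted over the list alone 12 rose and 1 fell, Gclc, which makes glutathione (log2 −0.65 ± 0.20, n = 2). The other negative member was Jag1 (−3.34 ± 1.82, n = 2), which did not pass and is described below. Oosp1, an oocyte secretory protein, had 0.90 ± 0.13, and Bmp15, an oocyte growth factor, 1.05 ± 0.21 (n = 3 each), both of which rose adjusted over the list alone. The shift held with an estimated correlation (adjusted p = 0.0262, 14 genes) and by fry (adjusted p = 0.000614). On the same 14 genes camera at the preset correlation gave an adjusted p = 8.55e-19. How small the p-value is thus rests on the correlation that is assumed between genes.

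Erythroid and blood cell markers shifted downward at day 4: 7 of 8 measured members were negative, with a median of −0.76 and a mean of −0.74 (adjusted p = 0.0216). Blvrb, a reductase of red cells, had log2 −1.46 ± 0.26 (n = 2) and fell adjusted over the list alone, 0 members passed over all probes by limma, and 7 did not pass either way. Not past the test were Gata1, the erythroid transcription factor (−0.57 ± 0.16, n = 2), Fech, the last enzyme of heme synthesis (−1.05 ± 0.35, n = 3), Ermap (−0.88 ± 0.35, n = 3) and Hba-a1, an alpha globin (−0.48 ± 0.72, n = 2). On the 5 members with values on all 6 arrays the shift did not pass at the preset correlation (adjusted p = 0.138) or with an estimated correlation (adjusted p = 0.448 with an estimated correlation), and it passed by fry (0.045). It was also lost without day 4 array 1 (adjusted p = 0.289) and without day 4 array 2 (adjusted p = 0.166). Smooth muscle and stromal markers shifted upward, with 6 of 7 positive, a median of 0.45 and a mean of 0.34 (adjusted p = 0.0239). Tpm1, a tropomyosin, had 0.64 ± 0.13 (n = 3) and rose adjusted over the list alone, and Tpm2 (0.71 ± 0.22, n = 2), Cnn2 (0.50 ± 0.34, n = 3) and Mylk (0.45 ± 0.34, n = 3) did not pass. On the 6 members with values on all 6 arrays that shift did not pass at the preset correlation (0.115), with an estimated correlation (adjusted p = 0.657 with an estimated correlation) or by fry (0.455), and it was lost without day 4 array 1 (0.245) or 2 (0.204), and without values the authors flagged (0.148).

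The other 20 lists did not pass at day 4. The imprinted fetal growth genes had a median of −0.44 (adjusted p = 0.0997), with 2 fallen adjusted over the list alone: Igf2, the fetal growth factor (−2.14 ± 0.33, n = 2), and Peg10 (−2.04 ± 0.51, n = 2). H19, the noncoding RNA next to Igf2, had −2.25 ± 1.08 (n = 2). Granulosa cell genes had a median of 0.22 (adjusted p = 0.143), with 3 of 12 risen adjusted over the list alone: Cdkn1b, an inhibitor of the cell cycle (0.75 ± 0.17, n = 2), Dhh, a hedgehog ligand (0.42 ± 0.11, n = 3), and Ptges, a prostaglandin synthase (0.87 ± 0.21, n = 2). TGF-beta and activin signalling (median 0.09, adjusted p = 0.143) had 2 risen adjusted over the list alone, Gdf9 and Bmp15, which the oocyte list also holds. Of the steroidogenic and theca cell genes (median 0.12, adjusted p = 0.366), Star, which brings cholesterol into mitochondria, had 0.52 ± 0.30 (n = 3), Cyp17a1 0.12 ± 0.53 (n = 2) and Hsd3b1 0.53 ± 0.60 (n = 3). Meiotic prophase genes had a median of −0.03 (adjusted p = 0.532), and Sycp3, of the synaptonemal complex, had 0.01 ± 0.13 (n = 3). Jag1, a Notch ligand, had −3.34 ± 1.82 (n = 2), a value that rests on day 4 array 3.

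Notch signalling had an adjusted p of 0.356, with an upward test, a median of 0.00 and a mean of −0.32. Cholesterol biosynthesis had a median of 0.08 (adjusted p = 0.209), extracellular matrix and basement membrane 0.04 (0.331) and PI3K and mTOR signalling 0.12 (0.149). Cell cycle and DNA replication had a median of −0.03, a mean of 0.01 and an upward test (adjusted p = 0.243), and ribosomal proteins a median of −0.18, a mean of −0.16 and an upward test (0.998). Apoptosis and oocyte loss (median −0.14, adjusted p = 0.748) had 1 member fallen adjusted over the list alone, Diablo, an inhibitor of apoptosis inhibitors (−0.48 ± 0.10). Oxidative phosphorylation had a median of −0.20 (adjusted p = 0.532), the proteasome −0.21 (0.207), chaperones −0.26 (0.354) and glycolysis and hypoxia response −0.26 (0.243). In the last list Pfkfb3, a regulator of glycolysis, rose adjusted over the list alone (0.93 ± 0.14). Immediate early and dissection stress genes had a median of −0.03, a mean of 0.06 and an upward test (adjusted p = 0.532), with Zfp36 risen adjusted over the list alone (1.82 ± 0.32). Vascular endothelial markers had a median of −0.24 (adjusted p = 0.287), with Podxl fallen adjusted over the list alone (−1.14 ± 0.18, n = 2). Fat tissue markers had −0.14 (0.532), and oviduct and duct epithelium markers 0.05 (0.369).

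**Figure D3:**
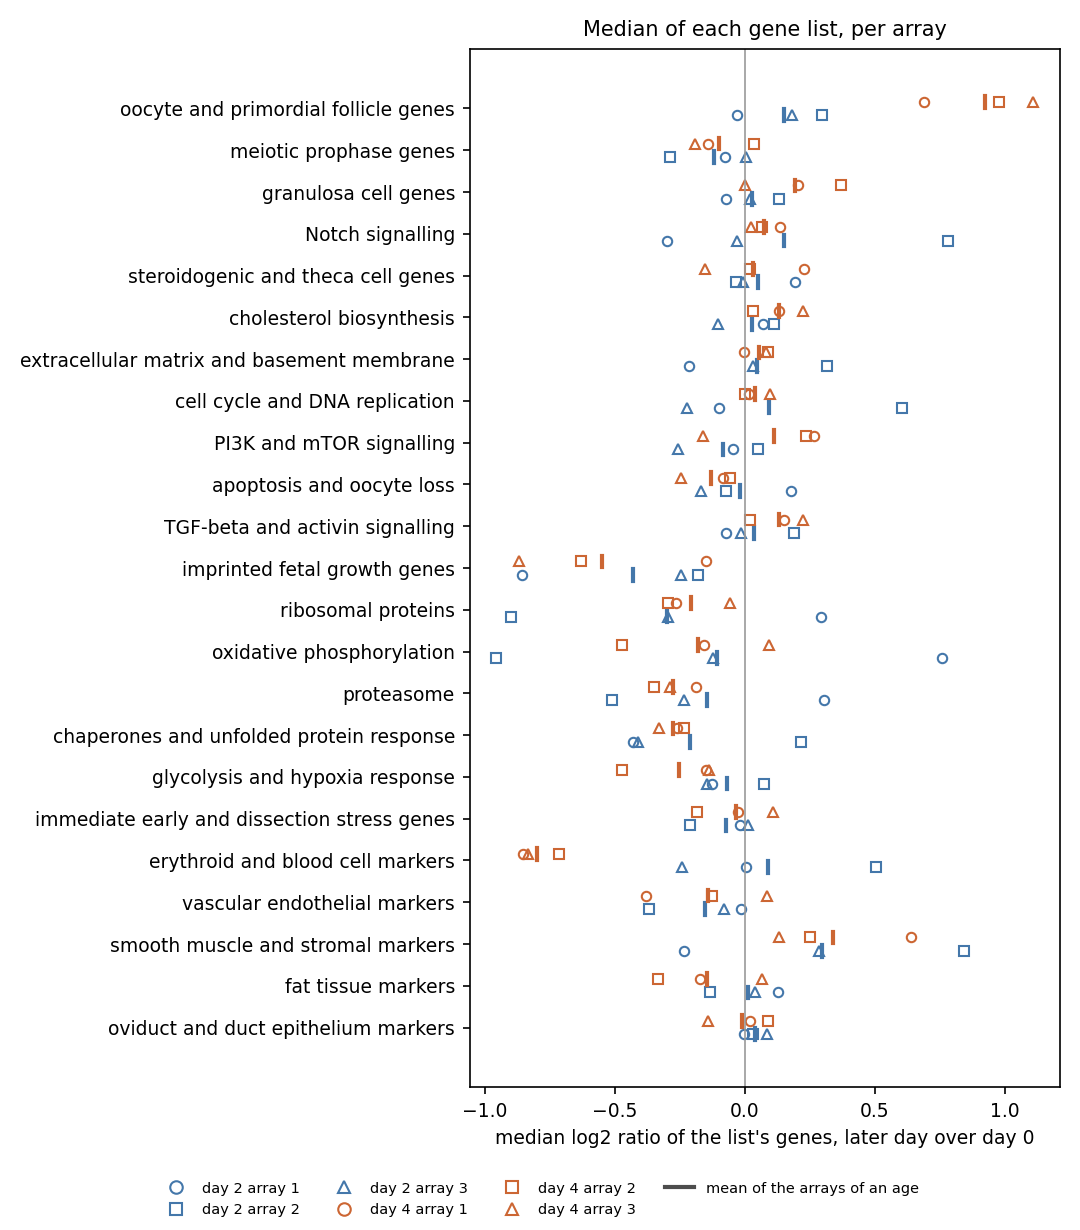
Median log2 ratio (later day over day 0) of the genes of each of the 23 tested lists on each of the 6 arrays, with a symbol per array and a bar at the mean of an age. The oocyte list lies between 0.69 and 1.11 on the day 4 arrays and between −0.03 and 0.30 on the day 2 arrays, and the erythroid list between −0.85 and −0.71 on the day 4 arrays and between −0.24 and 0.51 on the day 2 arrays.

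At day 2, at which the series text places follicle assembly, no single gene passed the test against day 0. The genes closest to it upward were Rgs12, a regulator of G-protein signalling (log2 1.04 ± 0.14), Appl1 (0.70 ± 0.10), Gdf9 (1.16 ± 0.18), Trpm7, an ion channel (0.92 ± 0.13), and Slx4ip (0.87 ± 0.15), each with n = 3. Downward they were Cct4, a subunit of a chaperonin (−0.86 ± 0.15), Rpl30, a ribosomal protein (−0.57 ± 0.11), peroxiredoxin 1, an antioxidant enzyme (−0.61 ± 0.12), transforming growth factor beta 1 induced transcript 4 (−0.96 ± 0.20) and craniofacial development protein 1 (−0.63 ± 0.15). The smallest adjusted p was 0.609. By limma 0 probes passed, with 231 at an unadjusted p under 0.05. With the sign of day 2 array 1 turned 0 passed (1884 at an unadjusted p under 0.05), and with that of day 2 array 2 turned 0 passed (1120), while spots kept as duplicates gave 19. The brightest Gdf9 probe had 1.30 ± 0.52, Bmp15 0.33 ± 0.21, Sycp3 −0.16 ± 0.13, Star 0.16 ± 0.30, Cyp17a1 0.10 ± 0.43, Hsd3b1 −0.06 ± 0.60, Jag1 −1.72 ± 1.49, H19 −1.04 ± 0.88 and Hba-a1 0.06 ± 0.59 (n = 3 each). Of the 37 gene values that the rule named for day 2, 19 kept their sign with day 2 array 1 or array 2 turned, among them the 10 genes closest to the test, and 18 did not. Those 10 were picked by small p-values, which favour like values on the 3 arrays, so that turning 1 could hardly change the sign. With array 1 turned H19 had 1.30, Hsd3b1 0.66, Igf2 0.14, Grb10 0.27, Hspd1 0.12, Tcp1 0.05, Ncapg −0.07 and Cyp17a1 −0.75. With array 2 turned the brightest Gdf9 probe had −0.36, Oas1d −0.08, Peg10 0.48, Sycp3 0.14, Hba-a1 −0.80, Cdc25a 0.02, Ube2c −0.17, S100a6 −0.11, Cnn1 −0.35 and Cnn2 −0.52. The day 2 value of Jag1 rests on day 2 array 3, without which it had 0.20 and Hsd3b1 0.42. Without day 2 array 1 H19 had 0.20, Hsd3b1 0.45 and Cyp17a1 −0.49, and without day 2 array 2 Hba-a1 had −0.55, Cnn1 −0.10 and Cnn2 −0.11.

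Among the lists at day 2, 5 of 23 passed. Of these, 4 had enough genes with values on all 6 arrays, where 2 passed at the preset correlation and 0 with an estimated correlation or by fry (camera and fry, 1 list each at an unadjusted p under 0.05). With the sign of day 2 array 1 or array 2 turned 6 and 5 lists passed. Without day 2 array 2, 3 lists passed, and without day 4 array 2, 2 did. The oocyte and primordial follicle genes shifted upward (median 0.11, mean 0.31, 14 of 21 positive, adjusted p = 5.86e-05). Adjusted over the list alone, 3 members rose and 0 fell by limma: Nlrp14 (1.78 ± 0.41), H1f8 (0.72 ± 0.12) and Oas1d (1.22 ± 0.30), with n = 3 each, and 0 passed over all probes. On the genes with values on all 6 arrays this shift had an adjusted p = 1.33e-06 at the preset correlation and 0.187 with an estimated correlation, and over all genes 0.0313 with the sign of day 2 array 1 turned and 0.93 with that of day 2 array 2 turned. Chaperones and unfolded protein response shifted downward (median −0.28, mean −0.31, 19 of 23 negative, adjusted p = 0.00528), and adjusted over the list alone Cct4 fell. Its other leading members, Cct5 (−0.41 ± 0.17), Tcp1 (−0.28 ± 0.14) and Hspd1 (−0.34 ± 0.17), did not pass. On the genes with values on all 6 arrays the chaperone shift had an adjusted p = 0.364 at the preset correlation and 0.581 with an estimated correlation, and with the sign of day 2 array 1 turned it was upward and not past the test (adjusted p = 0.315), while with that of day 2 array 2 turned it was downward and past it (0.00221). It was also lost without day 2 array 1 (0.781), day 4 array 2 (0.439), day 4 array 3 (0.388) or array 3 of both ages (0.371).

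Imprinted fetal growth genes shifted downward at day 2 (median −0.67, mean −0.57, 7 of 8 negative, adjusted p = 0.0218), with no member past the test over all probes or adjusted over the list alone. Igf2 had −1.09 ± 0.27, Ube3a, a ubiquitin ligase, −0.94 ± 0.27, Peg10 −0.98 ± 0.42 and Grb10, an adaptor of growth factor receptors, −0.41 ± 0.31. Too few of these genes had values on all 6 arrays for an estimated correlation. The imprinted list was upward with the sign of day 2 array 1 turned (adjusted p = 0.776) and had an adjusted p of 0.523 with that of day 2 array 2 turned, and it was lost without day 2 array 1 (0.454), day 2 array 2 (0.0818), both of these (0.63), day 4 array 3 (0.388) or array 3 of both ages (0.371). Cell cycle and DNA replication shifted upward (median 0.09, mean 0.07, 32 of 49 positive, adjusted p = 0.023), with no member past either test. Ncapg, a condensin subunit, had 0.36 ± 0.17, Ube2c 0.41 ± 0.18, Cdc25c, a phosphatase of the cell cycle, 0.32 ± 0.17, and Cdc25a −0.30 ± 0.12. On the genes with values on all 6 arrays this list had an adjusted p = 0.0946 at the preset correlation and 0.581 with an estimated correlation, and over all genes it was downward with the sign of day 2 array 2 turned (adjusted p = 0.0164) and downward without day 2 array 2 (0.286). It was lost with scale normalization (0.429), with the sign of day 2 array 1 turned (0.106) and without day 2 array 1 (0.0502), day 4 array 1 (0.0599) or day 4 array 2 (0.115), and it was downward without day 2 arrays 1 and 2 (0.42). Smooth muscle and stromal markers shifted upward (median 0.22, mean 0.22, 5 of 7 positive, adjusted p = 0.0205), with S100a6 at 0.68 ± 0.20, Tpm1 at 0.41 ± 0.13, Cnn2 at 0.37 ± 0.34 and Cnn1 at 0.22 ± 0.25, none past either test. On the genes with values on all 6 arrays that list had an adjusted p = 0.00423 at the preset correlation and 0.581 with an estimated correlation, and over all genes it passed upward with the sign of day 2 array 1 turned (0.0313) and was downward with that of day 2 array 2 turned (adjusted p = 0.523), and it was lost with scale normalization (0.0744) and without day 2 array 2 (0.624), day 2 array 3 (0.0715) or array 3 of both ages (0.152). The other 18 lists did not pass.

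Between day 2 and day 4, the oocyte and primordial follicle genes were higher at day 4 as a group. Of 21 members 19 were positive, with a median difference of 0.72 and a mean of 0.88 (log2, adjusted p = 1.19e-16). Adjusted over the list alone 5 rose and 0 fell (limma): Astl (2.41 ± 0.32), Oas1d (1.82 ± 0.42), H1f8 (1.68 ± 0.17), Oosp1 (0.87 ± 0.18) and Mos, a kinase of oocyte maturation (0.66 ± 0.17), with n = 3 per age except for Mos at day 4 (n = 2). The shift held with an estimated correlation (adjusted p = 0.0191) and by fry (0.00898), and with the sign of day 2 array 1 or array 2 turned (adjusted p = 4.73e-07 and 1.22e-08). On the 14 genes of the run with an estimated correlation, camera at the preset correlation gave an adjusted p = 4.21e-22. Here too the size of the p-value rests on the correlation assumed. Erythroid and blood cell markers were lower at day 4 in 8 of 8 members, with a median of −0.72 and a mean of −0.84 (adjusted p = 3.13e-05). Blvrb fell adjusted over the list alone (−1.64 ± 0.34, n = 2 at day 4), and Fech (−1.27 ± 0.50), Ermap (−1.24 ± 0.50) and Gata1 (−0.52 ± 0.21) did not pass. On the 5 members with values on all 6 arrays the erythroid shift had an adjusted p = 0.00405 at the preset correlation, 0.199 with an estimated correlation and 0.086 by fry, and over all genes it passed with the sign of day 2 array 1 or array 2 turned (0.0349 and 0.0386).

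No single gene passed between day 2 and day 4. By limma 0 probes passed, with 215 at an unadjusted p under 0.05 and a smallest adjusted p of 0.356, and spots kept as duplicates gave 57. With the sign of day 2 array 1 or array 2 turned 0 probes passed as well (931 and 721 at an unadjusted p under 0.05). Of the 5270 probes with values on all 6 arrays, the values of the ages did not overlap for 362 (6.9%) in the stated directions, where chance gives 10% for 3 arrays against 3. This share was not computed with a sign turned. The smallest p-values upward belonged to H1f8, Astl, Gdf9 (1.77 ± 0.26), 2'-5' oligoadenylate synthetase 1C (2.04 ± 0.34) and Trpm7 (1.25 ± 0.20). Downward they belonged to Krt18, an epithelial keratin (−1.45 ± 0.30), Blvrb, Tmx2 (−0.79 ± 0.20), Sh3d21 (−0.78 ± 0.19) and G protein-coupled receptor family C group 5 member B (−0.48 ± 0.13). The brightest Gdf9 probe had 2.09 ± 0.74, Bmp15 0.72 ± 0.30, Sycp3 0.17 ± 0.19, Igf2 −1.06 ± 0.43 and Hba-a1 −0.55 ± 0.93. Star had 0.37 ± 0.42, Cyp17a1 0.03 ± 0.68, Hsd3b1 0.59 ± 0.85, Jag1 −1.61 ± 2.35 and H19 −1.20 ± 1.39. Of the 25 gene values that the rule named here, 21 kept their sign with day 2 array 1 or array 2 turned. Hsd3b1 had −0.12 with array 1 turned, and Sycp3 had −0.13, Cyp17a1 −0.62 and Hba-a1 0.31 with array 2 turned. Without day 2 array 2 Hba-a1 had 0.07 and Cyp17a1 −0.51, without day 2 array 3 Cyp17a1 had −0.02, and without day 4 array 3 Star had −0.10. The other 21 lists did not pass, and with the sign of day 2 array 1 or array 2 turned 4 and 7 lists passed, as did 4 without day 2 array 1 and 7 without day 2 array 2.

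The 39 probes that rose by day 4 had positive mean log2 ratios at day 2 in the stated direction of the arrays, with a median of 0.84 at day 2 and 2.23 at day 4. Without day 2 array 3 all 39 were positive (median 0.89), with the sign of day 2 array 1 turned 38 were (median 0.34) and with that of day 2 array 2 turned 28 were (median 0.21). Among simulated unchanged arrays with 1 shared day 0 RNA, the 39 probes with the smallest p-values upward at day 4 included a mean of 25 that were positive at day 2 (highest 31), so that the count with array 2 turned lay within the simulated values. Of the 39 probes, 32 were positive on day 2 array 1, 38 on array 2 and 39 on array 3. By limma 0 probes passed in both comparisons, where independent lists and simulated unchanged arrays both gave 0, since none passed at day 2. Across 8135 probes, which are not independent replicates, the mean log2 ratios of the ages had r 0.653 and a covariance of 0.0737. The simulated arrays gave a mean r of 0.134 (highest 0.201) and a mean covariance of 0.0133 (highest 0.02). Without array 3 of both ages r was 0.506 (covariance 0.055), and with the sign of day 2 array 1 or array 2 turned it was 0.222 and 0.162 (covariance 0.0424 and 0.0283). With array 2 turned r thus lay under the highest simulated r, while the covariance lay above the highest simulated covariance. A dye effect common to the arrays would add to the counts and to this correlation and was not part of the simulation. The simulation also left day 2 arrays 1 and 2 unrelated, whereas in the data they ran opposite (r −0.675). It gave the day 0 RNA the same share of the variance on every array. The gap between the observed and the simulated values therefore does not by itself show a change shared by the ages.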

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

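The tests of a turned sign, of a trend with intensity, of a common dye effect and of the share of blood cells were chosen only after the results were seen, as were those of sign choices within an age and of the Cy3 share by intensity, with loess curves removed or with a sign turned. 2 gene lists stood out because the test of the difference between the ages passed. The oocyte and primordial follicle genes were higher at day 4 than at day 2 by a median of 0.72 (log2), and the erythroid and blood cell markers differed by a median of −0.72, with an adjusted p = 0.199 with an estimated correlation and 0.086 by fry on the 5 members with values on all 6 arrays. The list medians of the 3 day 4 arrays lay above those of the 3 day 2 arrays for the oocyte list and below them for the erythroid list. These 2 lists were picked by a test of this same difference, so that the separation is no further support. Chance gives such a separation in 10% of cases for 3 arrays against 3. Among the 10 splits of the 6 arrays into groups of 3, 7 gave at least the real 2 lists, with a highest other count of 7, and 10 gave at least the real 0 probes by limma (215 at an unadjusted p under 0.05), with a highest other count of 0. There are too few splits for a share under 0.05. The split with 7 lists set day 2 arrays 1 and 3 and day 4 array 3 against the others, and its count is several times the real one, which points to a structure of the arrays other than age. The 4 splits that kept array 3 of both ages, which share a day 0 RNA, together gave 7, 1, 1 and 0 lists. Without array 3 of both ages, 2 lists passed.

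The rise of the oocyte and primordial follicle genes by day 4 was set against a dye effect and a change in blood cells. A dye effect common to all arrays would cancel between day 4 and day 2, but there the median difference was 0.72 and the adjusted p was at most 0.0191 over all alternatives, which argues against it as the whole source. A lower share of blood cells would raise the genes of all other ovarian cell types alike, but the median of the 21 oocyte genes (0.88) exceeded that of 33 granulosa, theca, endothelial and stromal genes (0.12) by 0.76 (95% bootstrap interval over genes, which are not independent replicates, 0.39 to 2.38). In that order the 4 lists had medians of 0.22, 0.12, −0.24 and 0.45, which differ in direction and all lie under that of the oocyte list. A change with age in the oocytes or in their share of the ovary may underlie the rise, and that stays open as a hypothesis, since no test here set it apart from other differences between the day 2 and day 4 RNAs.

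Day 2 arrays 1 and 2 ran opposite to each other (r −0.675 across probes, which are not independent replicates). A trend of the ratios with intensity is argued against, since loess curves on intensity removed at most 1.2% of the variance of either array and left r at −0.67, and so is a turned sign of day 2 array 2, which correlated above 0 by both Pearson and Spearman with 4 of the other 4 arrays where a turned sign needs most below 0. A turned sign of day 2 array 1 could produce the pattern: it correlated above 0 by both with 2 of these 4 arrays and below 0 by both with 0, which decides nothing. A larger difference between the day 0 RNAs than between the day 2 RNAs is open too: in the stated directions the share of the arrays' difference in the Cy3 channel was 0.471 (95% bootstrap interval over probes 0.458 to 0.484), between the bounds of 0.33 and 0.67 set for it, and it was 0.508 with the loess curves removed and 0.338, 0.516 and 0.487 among the dimmest, middle and brightest probes in 3 groups of like size. With the sign of day 2 array 1 or array 2 turned the share was 0.493 and 0.507, also between the bounds. These 2 values add up to 1 by construction, so that they are 1 check. Another tissue or cell type in 1 of the RNAs is open as well (0 marker lists past the bound, described at the end), and these 3 explanations cannot be told apart here, since the count of array 1, the share and the lists did not reach a bound.

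Array 3 of both ages ran together (r 0.767 across probes, which are not independent replicates), above the r of 0.511 and 0.444 between day 4 array 3 and the other day 4 arrays. The day 0 RNA that they share may be the source: the share of their common deviation that lay in the Cy3 channel was 0.623 (95% bootstrap interval 0.485 to 0.763), and the bound set for it was 0.67. The deviation was taken from the other 4 arrays in their stated directions, and the share was not computed with a sign turned. A shared hybridisation or scan remains open beside it, since the deviations of their mean intensities correlated at 0.918. The shared RNA and such a shared step cannot be told apart here, and no biological explanation was tested.

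Within an age, turning the sign of 1 array at a time gives 4 choices of sign, too few for a share under 0.05. For day 4 against day 0, 1 of 4 choices gave at least the real 39 probes (highest other 0 by limma) and 1 of 4 at least the real 3 lists (highest other 1). For day 2 against day 0, 4 of 4 gave at least the real 0 probes by limma (231 at an unadjusted p under 0.05, highest other 0) and 3 of 4 at least the real 5 lists (highest other 6).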

How the results depend on the processing

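Settings with a turned sign, with pairs of arrays left out, without the authors' flagged values, with a loess curve removed or at the preset correlation on genes with values on all 6 arrays were chosen after seeing the data. The oocyte list kept its upward shift past the threshold at day 4 in every alternative, with adjusted p up to 0.0262 against day 0 and 0.0191 against day 2, and up to 0.93 at day 2. Of 263 values of genes called at day 4, 179 stayed past the threshold, 84 did not and 0 turned direction. Of the lists past the threshold, 53 of 63 values stayed so for day 4 against day 0 and 42 of 44 for day 4 against day 2. For day 2 against day 0, 65 stayed so, 30 did not and 6 turned direction. Median centring, the authors' value table, the median of spots, the filter on dim probes, the flags and the loess curve kept the counts of probes and lists within 1.5 times. The cause was not tested for the values that follow, except where fewer arrays, fewer genes or the threshold made the difference.

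Probes for day 4 against day 0 (39) were 96 with scale normalization, 126 with a trended and robust variance, 11 and 90 at adjusted p under 0.01 and 0.10, 374 with spots as duplicates, 166 with only the arrays of that age and also without day 2 arrays 1 and 2, 0 with the sign of day 2 array 2 turned and 0 without array 3 of both ages (limma, 897 and 433 at an unadjusted p under 0.05). Leaving out 1 array gave 0 to 71. Spots as duplicates gave 19 probes for day 2 against day 0 and 57 for day 4 against day 2, where the trended and robust variance gave 1.

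Lists for day 2 against day 0 (5) were 3 with scale normalization, 3 without day 2 arrays 1 and 2, and 2 to 5 with 1 array left out. On the genes with values on all 6 arrays they were 2 at the preset correlation, 0 with an estimated correlation and 0 by fry (1 each at an unadjusted p under 0.05). Lists for day 4 against day 0 (3) were 1 on those genes at the preset and with an estimated correlation, 5 without day 2 arrays 1 and 2, and 1 to 3 with 1 array left out. Lists for day 4 against day 2 (2) were 1 with an estimated correlation, 1 by fry, 4 and 7 with the sign of day 2 array 1 and array 2 turned, and 2 to 7 with 1 array left out.

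Directions turned in these lists (adjusted p). With 1 array left out, it ran from 0.00014 to 0.286 for cell cycle and 0.00276 to 0.439 for oxidative phosphorylation at day 2, and from 0.0157 to 0.942 and 0.00321 to 0.942 for day 4 against day 2. Without day 2 array 1, oxidative phosphorylation was upward for day 4 against day 2 (0.0306). Without day 2 array 2, cell cycle and DNA replication was downward at day 2 (0.286) and upward for day 4 against day 2 (0.0157), and oxidative phosphorylation upward at day 2 (0.0149). With the sign of day 2 array 1 turned, imprinted fetal growth genes (0.776) and chaperones (0.315) were upward at day 2 and oxidative phosphorylation upward for day 4 against day 2 (0.0275). With the sign of day 2 array 2 turned, Notch signalling (0.0198), cell cycle (0.0164) and stromal markers (0.523) were downward at day 2, ribosomal proteins (0.0198) and oxidative phosphorylation (0.0014) upward, and cell cycle upward for day 4 against day 2 (0.00207). Without day 2 arrays 1 and 2, cell cycle was downward at day 2 (0.42), and the lone day 2 array was assumed to vary like the others.

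The replicate number as a block gave 0 probes by limma (240 at an unadjusted p under 0.05) for day 4 against day 2. It gave 3 lists, 2 upward and 1 downward, of which 2 also passed without the block. Deviations of arrays with the same number correlated at 0.365, 0.053 and 0.515 across 5270 probes (not independent replicates). Those of arrays with different numbers correlated at −0.421 to 0.091. Array 3 of both ages shared a day 0 RNA, and whether the numbers pair the samples otherwise was not settled. Background correction, print-tip loess, filters on scanner background or scanner flags and a block for scan date or slide were not run, and day 0 RNA as a random block gave no estimate. Signal over background was not analysed here, and 997 probes of day 2 array 3 carried a flag read here from the values as low signal, against 0 to 212 on the other arrays.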

Other observations

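The test of other cell types was chosen before its result was seen, and the limit on low ratios was set after the values were seen. On array 3 of both ages, 9 probes had log2 ratios under −3 at both day 2 and day 4, down to −6.52, while on the other arrays they lay between −2.56 and 1.45. 3 of them had a gene name: Jag1, a Notch ligand (−5.57 at day 2 and −5.62 at day 4), Rprd1b, a regulator of transcription termination (−5.46 and −5.62), and Nin, a centrosome protein (−3.73 and −4.59). Array 3 of both ages had the same day 0 RNA.

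The difference between day 2 arrays 1 and 2 was searched for markers of another tissue or cell type in 1 of the RNAs. This search used the stated directions of both arrays and was not run with a sign turned. Of 5 marker lists with enough genes, 0 had a median difference beyond the range of 99% of random lists with at least 80% of members on that side. Smooth muscle and stromal markers came closest, with a median difference of −1.01 (array 1 minus array 2) and 85.7% of 7 members on that side, within a 99% range of −1.12 to 1.29. Another cell type in 1 of the RNAs therefore could be neither shown nor set aside, with 0 lists past the bound and this list outside the range of 95% of random lists (−0.80 to 0.94).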
